A study of Homo sapiens with 12 samples.

How the data were processed

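RNA was measured in 12 cultures of erlotinib-resistant PC9 cells in a design that crosses erlotinib with YF454A: control, erlotinib (5 µM), YF454A (0.2 µM) and both, collected after 12 h, with 3 arrays in each group. Per the labels' protocols, total RNA was extracted with Trizol, turned into biotinylated cRNA and hybridised to Affymetrix Human Transcriptome Arrays. Groups and replicate numbers were taken from the sample labels. The deposited values are log2 intensities that the authors made by robust multi-array averaging (RMA), which corrects background, quantile normalizes and summarises probes, with the oligo package in R 3.2.2, per the submitters' processing notes. The parameters of that step, the oligo version and the genome build of the probe annotation are not given in the sources used here. Quantile normalization gives all arrays nearly the same distribution of probe values, so a change in the total amount of RNA per cell cannot be seen, and changes of dim genes can be compressed.

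The table held 70523 rows, of which 67528 were transcript clusters and 2995 control probe sets and spike-ins. In the platform annotation 23781 transcript clusters had 1 gene symbol, 1543 had several and 42204 had none. Clusters with 1 symbol were tested, and where a gene had several, the one with the highest mean over all arrays was kept, which left 22465 genes. Of these, 20297 matched a RefSeq gene (assembly GRCh38.p14, used for names and gene types only), and 16838 of them are protein coding. Some of the genes fixed for naming are not reported here. No per-sample column was left out.

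A linear model with a mean for each group was fitted to the 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package (version 1.17.8) for reading, and 6 comparisons were tested: each drug and the combination against control, the combination against each drug, and the interaction. Tests were two-sided moderated tests, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. The residual degrees of freedom were 8, the prior ones 4.19 and the median residual SD 0.082. In 27 gene lists (563 entries, 509 measured) the shift against all other genes was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with a correlation estimated for each list and fry, which asks whether a list's own genes move on balance to one side. In each list past the camera threshold, the median, the mean and camera's direction had the same sign; among lists not past it they differed in 2, 5, 5, 3, 8 and 6 lists, in the order of the comparisons above, and no direction is given for these. Members of a list that passed are counted over all genes and adjusted over the list alone. Lists share members, and members with closely similar transcripts, such as the AKR1C genes, the MT1 genes and histones, are not separate measurements.

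Groups, lists, tests, the genes to be named and most alternatives were fixed before the data were examined. Named genes are the 8 largest rises and 8 largest falls per comparison among genes past the threshold whose arrays do not overlap between the groups (for the interaction, past the threshold alone), provisional gene names left out, up to 4 members per list and comparison, and 16 fixed genes. Of values from 3 arrays against 3, 10% do not overlap by chance. Words such as largest refer to this selection.

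Alternatives tried were a filter on dim genes, all transcript clusters, the mean of all clusters of a gene, median centring of arrays, a further quantile normalization, a trended and robust prior, array weights, the replicate number as a block, a 2-fold minimum, a fit of the 6 compared arrays alone and leaving out each array. The fit was tested on simulated data made for each comparison over 22465 genes with 50 changed genes of each size. Changes of 0.3 were recovered in 52% (erlotinib), 40% (YF454A), 52% (combination), 60% (combination against erlotinib), 52% (combination against YF454A) and 12% (interaction) of genes, and changes of 0.5 in 96%, 90%, 96%, 92%, 94% and 76%. False calls made up 2.82% to 6.25% of the calls. The simulated noise was normal and independent for each gene and array, and fewer genes changed than were called in the data. These shares may therefore not carry over to the real arrays, whose deviations were partly shared. The check of the cell line labels was an exact permutation test over 220 regroupings. Figures were drawn with matplotlib 3.10.9.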

Results

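Transcript levels were measured in 12 cultures of erlotinib-resistant PC9 cells, a human non-small cell lung cancer line that carries an activating deletion in EGFR. The cells received no drug (control), the EGFR kinase inhibitor erlotinib at 5 µM, YF454A at 0.2 µM, which the labels describe as a histone deacetylase (HDAC) inhibitor, or both drugs (combination), and were collected after 12 h. Each of the 4 groups held 3 arrays, described in the series design as independent biological replicates. The arrays were Affymetrix Human Transcriptome Arrays, and 22465 genes were tested in 6 comparisons. Array medians lay between 2.73 and 2.82 on the log2 scale. Across transcript clusters, which are not independent replicates, the correlation was 0.997 to 0.999 between arrays of one group and 0.986 to 0.998 between arrays of different groups. The first principal component held 63.7% of the variance and parted the 6 arrays without YF454A from the 6 with it, with no overlap. The number of arrays limits the precision of every value. Gene values are log2 intensities with SD over 3 arrays, changes are log2 differences ± standard error from limma, and adjusted p-values are limma's unless camera is named.

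The labels were not uniform. Source names and growth protocols gave resistant PC9 cells for all arrays, while the descriptions of the control arrays and the treatment protocol named A549, another lung cancer line. A fixed list of 15 genes abundant in A549 cells, among them AKR1B10, GPX2 and ALDH1A1, had a mean log2 level of 5.56 in the controls and 5.50 in the 9 treated arrays. The difference was 0.054 (95% interval -0.179 to 0.286, two-sided exact permutation p = 0.609 over 220 regroupings). The treated arrays were not alike: against control the list mean moved by 0.165 with erlotinib, -0.205 with YF454A and -0.122 with the combination. These shifts partly cancel in the pooled difference and widen its interval, so the interval and p also reflect the drugs. The treatment protocol also gave erlotinib as 5 nM, against 5 µM in the series design, and the controls were described both as untreated and as vehicle-treated. The micromolar dose is used here.

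The first comparison asked what erlotinib changed in cells selected for resistance to it. Genes driven by ERK, the kinase cascade downstream of EGFR, fell. DUSP6, which encodes an ERK phosphatase (transcript cluster TC12001796.hg.1), went from 6.14 ± 0.165 in control to 5.17 ± 0.083 with erlotinib (SD, n = 3 each). FOSL1 fell by 0.81 ± 0.087, IER3 by 0.81 ± 0.11, SPRY4 by 0.60 ± 0.059 and MYC by 0.44 ± 0.063, with adjusted p from 4.31e-05 (SPRY4) to 0.000662 (MYC). Of the 20 genes in the list of ERK pathway output, 16 fell (17 adjusted over the list alone). Among EGFR family ligands, HBEGF fell 3.02-fold (log2 change -1.59 ± 0.076, adjusted p = 2.93e-07), EREG by 0.80 ± 0.089 and NRG1 by 0.59 ± 0.058, and 4 of 8 ligands fell (5 fell and 1 rose adjusted over the list alone). Both lists were lower by camera, with adjusted p = 1.29e-20 for ERK output and 0.000872 for the ligands. With an estimated correlation ERK output stayed past the threshold (adjusted p = 0.0287) and the ligands did not (adjusted p = 0.0538 with an estimated correlation).

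Genes of cell proliferation fell as well. MCM10 fell by 0.72 ± 0.052 (adjusted p = 5.47e-06), and GINS2 and CDC45, which also take part in starting replication forks, fell by 0.68 ± 0.068 and 0.63 ± 0.053. Of 34 genes of DNA replication and S phase, 30 fell (33 adjusted over the list alone), with a median of -0.42. RAD54L, a recombination factor, fell by 0.71 ± 0.058 and the helicase gene BLM by 0.66 ± 0.080, and 14 of 19 genes of homologous recombination and the Fanconi anaemia pathway fell (14 adjusted over the list alone). In the list of MYC and ribosome biogenesis genes 19 of 24 fell (23 adjusted over the list alone), including LYAR (-0.65 ± 0.065) and ODC1 (-0.57 ± 0.048), the first enzyme of polyamine synthesis. Camera gave adjusted p = 7.89e-31 for replication, 3.47e-11 for recombination and 3.63e-21 for MYC and ribosome biogenesis. Replication and ribosome biogenesis also passed with an estimated correlation (0.0287 for each), and recombination had adjusted p = 0.112 with an estimated correlation. Mitosis genes were lower, with UBE2C at -0.45 ± 0.073 and 6 of 31 lower (10 lower and 1 higher adjusted over the list alone), and the call of that list (camera adjusted p = 0.00783; adjusted p = 0.572 with an estimated correlation) was lost after a further quantile normalization (0.128), with fry (0.163) and without 4 arrays chosen after the data were seen (0.716).

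Other genes rose with erlotinib. ASNS, asparagine synthetase, rose from 6.03 ± 0.085 to 7.27 ± 0.056 (SD, n = 3 each), and PSAT1, of serine synthesis, and DDIT4 rose by 0.69 ± 0.053 and 0.63 ± 0.054. In the list of the unfolded protein and amino acid stress response, 8 of 21 genes rose and 2 fell (12 and 2 adjusted over the list alone), and the list was higher (camera adjusted p = 8.36e-07; adjusted p = 0.0287 with an estimated correlation). Of 20 targets of the oxidative stress factor NRF2, 9 rose (15 adjusted over the list alone), led by AKR1B10 at 0.78 ± 0.071 (camera adjusted p = 1.05e-11; adjusted p = 0.0627 with an estimated correlation). AKR1C1 (0.45 ± 0.056) and AKR1C2 (0.48 ± 0.056) also rose, but their transcripts are so similar that they cannot be read as separate measurements. The genes abundant in A549 cells share 5 members with the NRF2 list and were also higher: 5 of 15 rose (5 adjusted over the list alone; camera adjusted p = 0.000816; adjusted p = 0.166 with an estimated correlation). The largest rises were of CYP1B1 (3.33-fold, 1.74 ± 0.15, adjusted p = 2.23e-05), a cytochrome P450, STEAP4 (1.72 ± 0.15), SLC16A4 (1.51 ± 0.086) and KMO (1.41 ± 0.10). The largest falls beside HBEGF were of AADAC (-1.60 ± 0.15) and the noncoding LINC00941 (-1.49 ± 0.069).

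Shifts were also seen in further lists. Glycolysis genes were lower, with 8 of 21 past the test (9 adjusted over the list alone) and HK2, hexokinase 2, at -0.91 ± 0.073 (camera adjusted p = 0.000165; adjusted p = 0.221 with an estimated correlation). Inflammatory cytokine genes were lower, with LIF at -0.87 ± 0.10 and IL11 at -0.68 ± 0.091, 7 of 21 lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.0158; adjusted p = 0.345 with an estimated correlation). Epithelial genes were higher, with TJP3 at 0.58 ± 0.082 and 7 of 22 higher (9 adjusted over the list alone; camera adjusted p = 0.000498; adjusted p = 0.221 with an estimated correlation). Mesenchymal genes were lower, with TNC at -0.46 ± 0.051 and 4 of 18 lower (4 adjusted over the list alone; camera adjusted p = 0.0297; adjusted p = 0.221 with an estimated correlation; 0.0546 without the same 4 arrays). Cholesterol synthesis and uptake genes (4 of 19 higher and 1 lower; 7 and 1 adjusted over the list alone), interferon response genes (2 of 23 higher; 2 adjusted over the list alone), antigen presentation genes (5 of 16 higher and 1 lower; 5 and 1 adjusted over the list alone) and genes often raised by HDAC inhibitors (4 of 19 higher; 5 adjusted over the list alone) were higher, with camera adjusted p = 0.000141, 0.00133, 0.00332 and 0.00598. None of these 4 passed with an estimated correlation (adjusted p = 0.118, 0.221, 0.256 and 0.302 with an estimated correlation). Receptor tyrosine kinase genes went both ways: MET fell by 0.76 ± 0.066 and EPHA2 by 0.66 ± 0.055, ERBB3 rose by 0.51 ± 0.045, and 2 of 28 rose and 3 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.341).

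Erlotinib changed 2609 of the 22465 genes at adjusted p under 0.05 by limma, 969 higher and 1640 lower, of which 29 changed at least 2-fold. Camera called 17 of the 27 lists in this comparison, and 4 with an estimated correlation. EGFR itself was lower by 0.15 ± 0.045 (adjusted p = 0.0419), a call lost without control 1 (0.12), control 2 (0.0592), control 3 (0.105), erlotinib 1 (0.0791), erlotinib 2 (0.158) or erlotinib 3 (0.0864), and also after median centring (0.0509), a further quantile normalization (0.166), a fit of the 6 compared arrays alone (0.0978) or without the same 4 arrays (0.167).

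**Figure D1:**
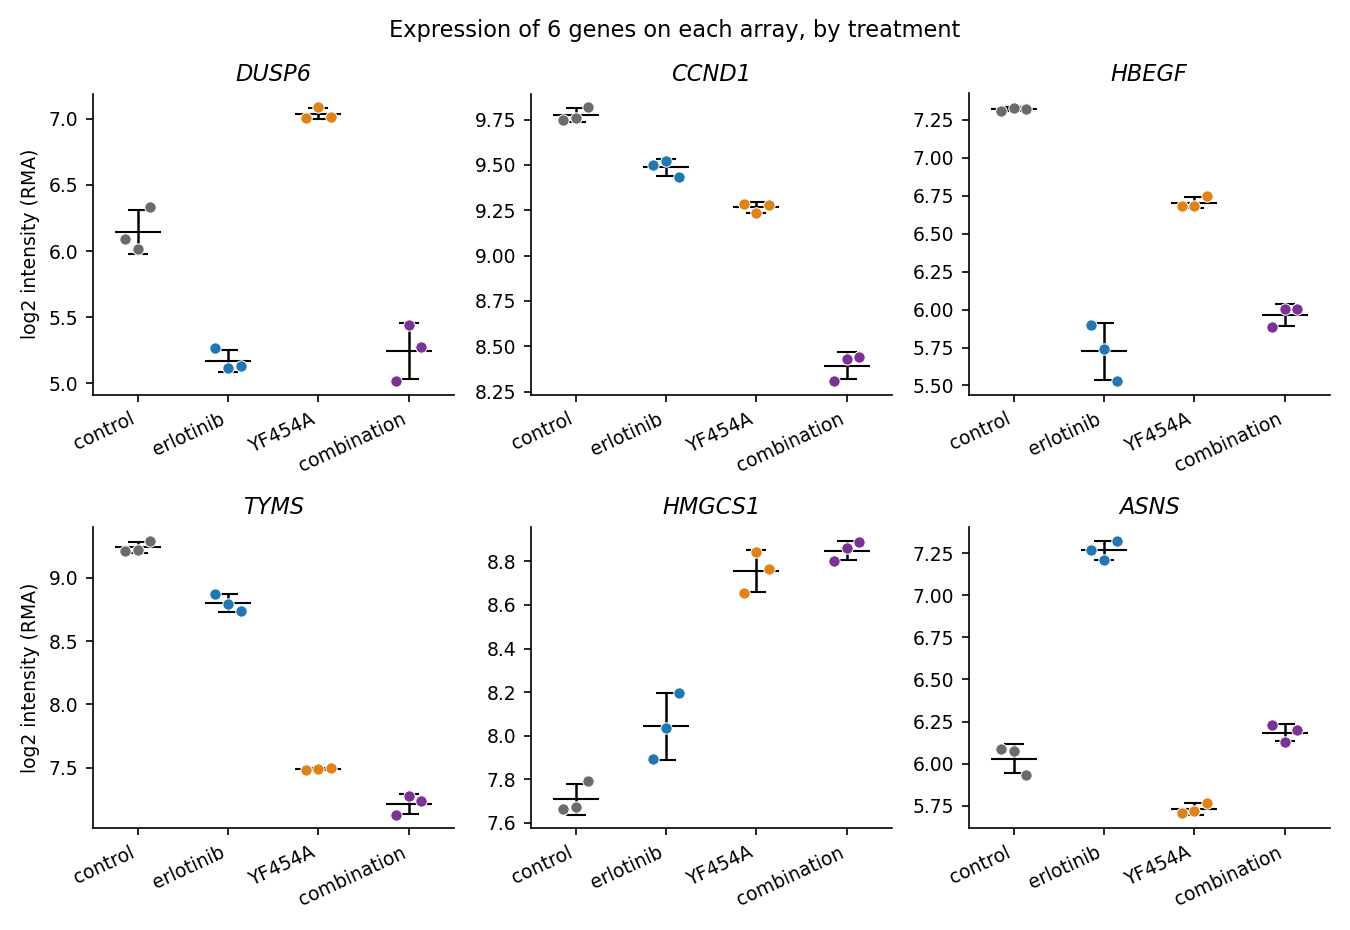
Log2 RMA intensity of 6 genes (vertical axes, each with its own range) on each of the 3 arrays per treatment (points), with the mean (long line) and SD (bars). DUSP6 stands at 6.14 in control, 5.17 with erlotinib, 7.04 with YF454A and 5.24 with the combination, and TYMS at 9.24, 8.80, 7.49 and 7.21 in the same order.

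YF454A alone changed more genes than erlotinib at the same threshold. The largest rise was of WIPI1, which encodes a protein of early autophagosomes, from 4.64 ± 0.117 to 7.33 ± 0.050 (SD, n = 3 each), or 6.43-fold (adjusted p = 8.55e-10). FBXO32, a ubiquitin ligase subunit, rose by 2.10 ± 0.048 and CALCOCO1, an autophagy receptor, by 2.03 ± 0.067. CDCA7 fell by 2.25 ± 0.099, MLKL, the effector of necroptosis, by 2.21 ± 0.094 and DOCK10 by 2.15 ± 0.086. Among genes often raised by HDAC inhibitors, SAT1 rose by 0.99 ± 0.076, MT1X by 0.89 ± 0.071 and TXNIP by 0.85 ± 0.093, and 10 of 19 rose (11 adjusted over the list alone; camera adjusted p = 2.94e-05; adjusted p = 0.341 with an estimated correlation). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 0.30 ± 0.073 (adjusted p = 0.00687).

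DNA replication genes fell with YF454A too. CCNE2 fell by 1.87 ± 0.11, TYMS, thymidylate synthase, 3.36-fold (-1.75 ± 0.053, adjusted p = 1.08e-09) and MCM3 by 1.40 ± 0.055, and 32 of 34 genes fell (32 adjusted over the list alone), with a median of -0.72. Recombination and Fanconi anaemia genes (14 of 19 lower; 15 lower and 1 higher adjusted over the list alone; BRIP1 at -0.95 ± 0.11) and the MYC and ribosome biogenesis list (18 of 24 lower and 1 higher; 19 and 1 adjusted over the list alone; UTP20 at -1.42 ± 0.12) were also lower. Camera gave these 3 lists adjusted p = 8.35e-24, 1.49e-05 and 3.65e-08, and none passed with an estimated correlation (adjusted p = 0.101, 0.36 and 0.341 with an estimated correlation). Of 6 histone genes with polyadenylated transcripts 5 fell (5 adjusted over the list alone), with H2BC11 at -1.14 ± 0.10 (camera adjusted p = 0.00596; adjusted p = 0.341 with an estimated correlation).

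Cholesterol genes rose with YF454A. MSMO1 rose by 1.13 ± 0.094, HMGCS1 by 1.04 ± 0.075 and SQLE, squalene epoxidase, by 0.87 ± 0.064, and 13 of 19 genes rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 3.65e-08; adjusted p = 0.101 with an estimated correlation). Epithelial genes were higher, with ELF3 at 0.81 ± 0.060 and CDH1, E-cadherin, at 0.56 ± 0.042, 9 of 22 higher and 4 lower (10 and 4 adjusted over the list alone; camera adjusted p = 0.0269; adjusted p = 0.443 with an estimated correlation). NRF2 targets were lower, with the glutathione peroxidase gene GPX2 at -1.06 ± 0.087, 10 of 20 lower and 1 higher (11 and 3 adjusted over the list alone). Also lower were the genes abundant in A549 cells (7 of 15 lower; 7 adjusted over the list alone) and inflammatory cytokines (8 of 21 lower and 2 higher; 10 and 2 adjusted over the list alone; PTGS2 at -1.24 ± 0.096). Camera gave these adjusted p = 0.00383, 0.0152 and 0.0142 (adjusted p = 0.401, 0.36 and 0.401 with an estimated correlation).

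Within the ERK list the genes parted. DUSP5 rose by 1.13 ± 0.079, DUSP6 by 0.89 ± 0.10 and MYC by 0.27 ± 0.063. FOSL1 fell by 0.87 ± 0.087 and CCND1, cyclin D1, by 0.51 ± 0.049. In all, 7 of 20 rose and 8 fell (7 and 8 adjusted over the list alone; camera adjusted p = 0.845). Mitosis genes parted too, with FOXM1 at -0.89 ± 0.072 and NEK2 at 0.82 ± 0.067, 8 of 31 higher and 10 lower (8 and 10 adjusted over the list alone; camera adjusted p = 0.845). HDAC9 fell by 0.64 ± 0.048 and HDAC5 rose by 0.54 ± 0.061, with 4 of 13 histone deacetylase genes higher and 3 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.561). Of 29 neuronal genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.561), with MAPT at 0.97 ± 0.070. Of 16 heat shock protein genes 5 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.84), with HSPA1A, nearly identical in sequence to HSPA1B, at 0.87 ± 0.063. Among 10 leukocyte markers 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.643), led by CD68, a lysosomal membrane protein also made outside leukocytes, at 0.71 ± 0.077.

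YF454A changed 6609 genes by limma, 3338 higher and 3271 lower, of which 329 changed at least 2-fold. Camera called 10 of the 27 lists, and 0 with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 15.

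With both drugs, changes against control were compared next. WIPI1 rose 7.22-fold (2.85 ± 0.074, adjusted p = 1.83e-10), PAIP2B by 2.83 ± 0.092, HEG1 by 2.81 ± 0.058 and IFI6, an interferon-induced gene, by 2.43 ± 0.086. NAV3 fell 8.70-fold (-3.12 ± 0.099, adjusted p = 6.51e-10), MLKL by 2.65 ± 0.094 and DOCK10 by 2.63 ± 0.086. In the ERK list PHLDA1 fell by 1.41 ± 0.061, CCND1 from 9.78 ± 0.037 to 8.39 ± 0.074 (SD, n = 3 each) and FOSL1 by 1.33 ± 0.087, and 16 of 20 fell and 3 rose (16 and 3 adjusted over the list alone). Of 8 EGFR ligands 6 fell (6 adjusted over the list alone), with NRG1 at -1.04 ± 0.058. Camera gave adjusted p = 2.71e-08 for ERK output and 0.000631 for the ligands (adjusted p = 0.163 and 0.0651 with an estimated correlation).

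In the same comparison TYMS fell 4.08-fold (-2.03 ± 0.053) and CCNE2 by 1.95 ± 0.11, and 32 of 34 replication genes fell and 1 rose (32 and 1 adjusted over the list alone). UTP20, a ribosome biogenesis factor, fell by 2.09 ± 0.12, and 21 of 24 genes of its list fell (22 adjusted over the list alone). In the same comparison 14 of 19 recombination genes fell and 2 rose (14 and 2 adjusted over the list alone; CHEK1 at -0.99 ± 0.076). HMGCS1 rose by 1.14 ± 0.075 among 15 of 19 cholesterol genes that rose (15 adjusted over the list alone). TXNIP rose by 1.28 ± 0.093 among 13 of 19 genes often raised by HDAC inhibitors (13 adjusted over the list alone). LIF fell by 1.77 ± 0.10 among 9 of 21 cytokine genes that fell, with 1 higher (9 and 1 adjusted over the list alone). IL6 was the cytokine gene that rose, by 1.17 ± 0.067. Camera adjusted p-values were 1.54e-21 for replication, 7.07e-16 for ribosome biogenesis, 1.65e-05 for recombination, 3.57e-08 for cholesterol, 1.72e-06 for the HDAC inhibitor genes and 0.0133 for cytokines. None passed with an estimated correlation (in the same order, adjusted p = 0.0651, 0.0651, 0.375, 0.0651, 0.163 and 0.528 with an estimated correlation).

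BMF, which encodes a BH3-only inducer of apoptosis, rose by 1.34 ± 0.073 with the combination and BCL2L11 (BIM) by 0.60 ± 0.065, while BID fell by 1.12 ± 0.062. In the list of the BCL2 family and inhibitors of apoptosis 5 of 18 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.854). Of 17 p53 targets 9 rose and 3 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.0606), with TP53INP1 at 1.30 ± 0.083 and MDM2 at -0.64 ± 0.074. Of 11 cell cycle inhibitors 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.336), with RBL1 at -1.19 ± 0.089. COL1A1 was the 1 of 10 fibroblast markers that rose (0.36 ± 0.071; 1 adjusted over the list alone; camera adjusted p = 0.762). AXL fell by 0.38 ± 0.066 (adjusted p = 0.000459), and for IGF1R (0.06 ± 0.046) and MCL1 (-0.06 ± 0.048) the change did not pass. The combination changed 7427 genes by limma, 3706 higher and 3721 lower, of which 563 changed at least 2-fold. Camera called 8 lists, and 0 with an estimated correlation (6 at an unadjusted p under 0.05), and fry called 17.

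**Figure D2:**
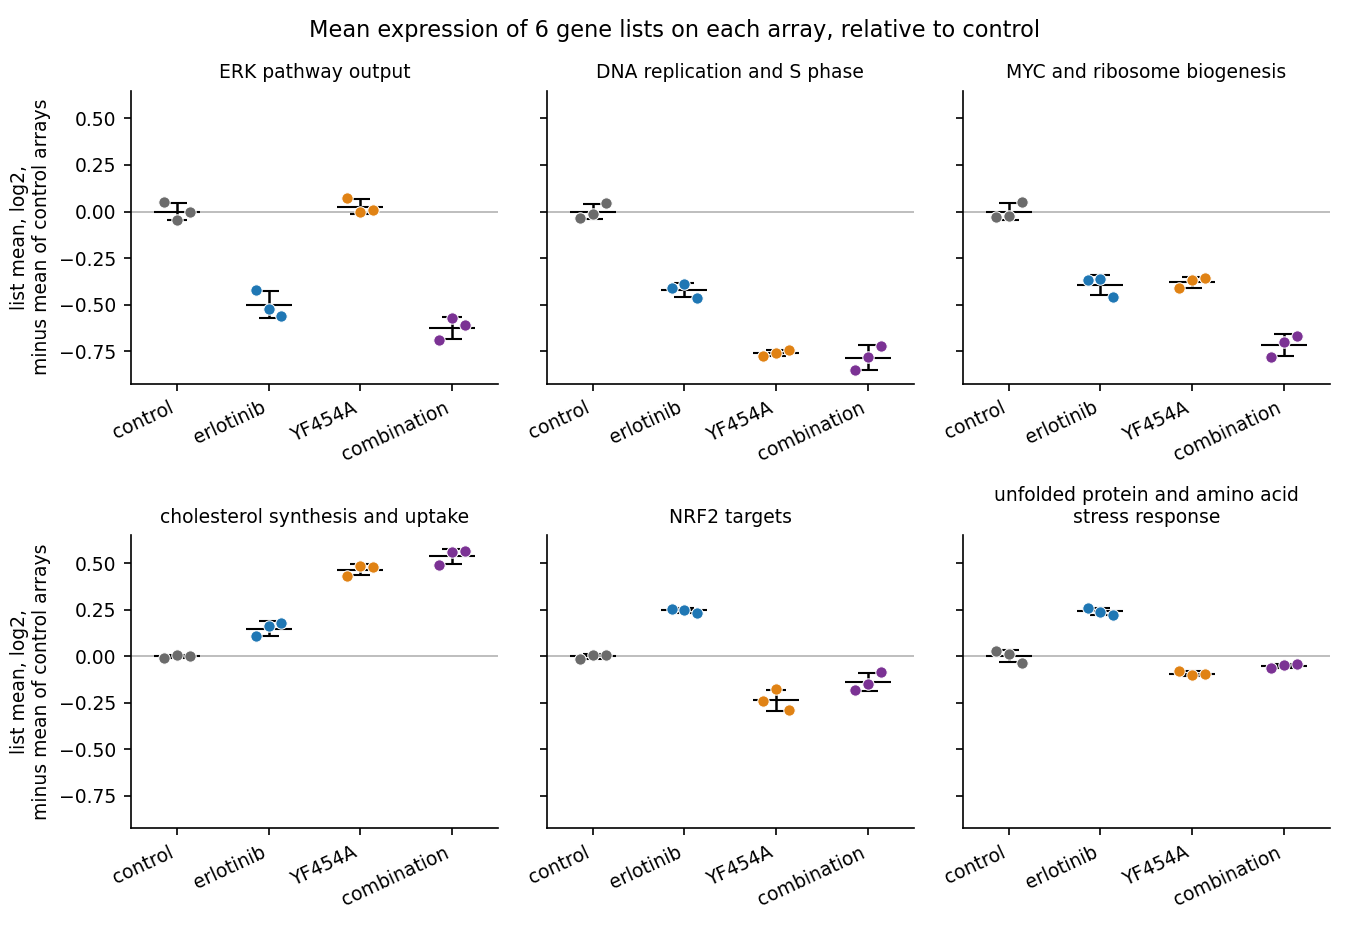
Mean log2 level of 6 gene lists on each of the 3 arrays per treatment, minus the mean of the control arrays (vertical axis; points are arrays, long lines means and bars SD). ERK pathway output stands at -0.50 with erlotinib, 0.025 with YF454A and -0.62 with the combination, and DNA replication and S phase at -0.42, -0.76 and -0.78.

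Adding YF454A to erlotinib asked what the HDAC inhibitor changed in the presence of the EGFR inhibitor. PAIP2B rose by 2.85 ± 0.092, DENND2C by 2.74 ± 0.10 and TNFSF9, the ligand of the costimulatory receptor 4-1BB on T cells, by 2.53 ± 0.15. DOCK10 fell by 2.50 ± 0.086 and KMO, which had risen with erlotinib alone, fell 4.40-fold (-2.14 ± 0.10, adjusted p = 2.47e-08). CCND1 fell by 1.09 ± 0.049 and EGFR by 0.30 ± 0.045, and MET was higher by 0.28 ± 0.066 (adjusted p = 0.00542). Genes of the stress and NRF2 lists fell: SLC7A11, the cystine transporter, by 1.38 ± 0.092, XBP1 by 1.26 ± 0.056, ASNS by 1.08 ± 0.054 and the exporter gene ABCC2 by 1.17 ± 0.064. Of the 21 stress response genes 12 fell and 5 rose (12 and 7 adjusted over the list alone), and of the 20 NRF2 targets 12 fell and 2 rose (12 and 2 adjusted over the list alone). Camera gave adjusted p = 0.00546 and 5.1e-05 (adjusted p = 0.326 and 0.329 with an estimated correlation).

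In the same comparison TYMS fell by 1.59 ± 0.053 and 23 of 34 replication genes fell and 2 rose (24 and 2 adjusted over the list alone). NCL, nucleolin, fell by 0.71 ± 0.042 and 16 of 24 ribosome biogenesis genes fell (18 adjusted over the list alone). AKR1B10 fell by 1.01 ± 0.071 among 7 of 15 genes abundant in A549 cells that fell (7 adjusted over the list alone). INSIG1 rose by 0.81 ± 0.068 and 14 of 19 cholesterol genes rose and 1 fell (15 and 2 adjusted over the list alone). MT1X rose by 0.96 ± 0.071 and 12 of 19 genes often raised by HDAC inhibitors rose (13 adjusted over the list alone). ALDOC, a glycolytic aldolase, rose by 1.13 ± 0.057 and 9 of 21 glycolysis genes rose and 1 fell (9 and 1 adjusted over the list alone). Camera adjusted p-values for these 6 lists were 1.14e-08, 1.49e-06, 0.00386, 1.49e-06, 2.06e-05 and 0.0323 (adjusted p = 0.326, 0.326, 0.326, 0.313, 0.326 and 0.732 with an estimated correlation). The glycolysis call was lost without the same 4 arrays (0.183). The combination differed from erlotinib in 6704 genes by limma, 3570 higher and 3134 lower, of which 365 changed at least 2-fold. Camera called 8 lists, and 0 with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 19.

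Adding erlotinib to YF454A asked what erlotinib still changed in the presence of the HDAC inhibitor. DUSP6 fell from 7.04 ± 0.043 to 5.24 ± 0.214 (SD, n = 3 each), or 3.47-fold (adjusted p = 2.33e-06). PHLDA1 fell by 0.97 ± 0.061, MYC by 0.89 ± 0.063, CCND1 by 0.87 ± 0.049 and SPRY4 by 0.84 ± 0.059, and 18 of 20 ERK genes fell (18 adjusted over the list alone; camera adjusted p = 1.56e-37; adjusted p = 0.0148 with an estimated correlation). The ligand EREG fell by 1.14 ± 0.089 and HBEGF by 0.74 ± 0.076, and 4 of 8 ligands fell (4 adjusted over the list alone; camera adjusted p = 0.000239; adjusted p = 0.0381 with an estimated correlation). EGFR fell by 0.43 ± 0.045 (adjusted p = 0.000145) and MET by 0.52 ± 0.066, and in the MYC and ribosome biogenesis list 14 of 24 fell (20 adjusted over the list alone; camera adjusted p = 2.66e-23; adjusted p = 0.0381 with an estimated correlation).

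The replication list was not called here (camera adjusted p = 0.2): CDC6 fell by 0.32 ± 0.048, and 3 of 34 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.019. The largest rises were of STEAP4 (1.52 ± 0.15) and CFB, complement factor B (2.83-fold, adjusted p = 4.18e-07), and the epithelial factor ELF3 rose by 0.89 ± 0.060 and BMF by 0.71 ± 0.073. Interferon response genes were higher, with IFI6 at 1.03 ± 0.086 and 3 of 23 higher (3 adjusted over the list alone). Also higher were antigen presentation genes (2 of 16 higher; 3 adjusted over the list alone), NRF2 targets (5 of 20 higher and 1 lower; 9 and 2 adjusted over the list alone; HMOX1 at 0.46 ± 0.068), genes often raised by HDAC inhibitors (3 of 19 higher; 4 adjusted over the list alone), polyadenylated histones (1 of 6 higher; 2 adjusted over the list alone) and genes abundant in A549 cells (2 of 15 higher; 2 adjusted over the list alone). Camera adjusted p-values for these 6 lists were 0.000302, 0.00268, 0.00116, 0.00137, 0.00157 and 0.04, and none passed with an estimated correlation (adjusted p = 0.298, 0.44, 0.44, 0.44, 0.298 and 0.44 with an estimated correlation). The call for the genes abundant in A549 cells was also lost with arrays centred on their medians (0.0791), with fry (0.0582) and without the same 4 arrays (0.0957).

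The combination differed from YF454A in 1068 genes by limma, 384 higher and 684 lower, of which 14 changed at least 2-fold. Camera called 9 lists, and 3 with an estimated correlation. The count of genes fell to 590 without combination 1, 572 without combination 2, 684 without YF454A 2 and 566 without YF454A 3. It was 795 without combination 3 and rose to 1127 without YF454A 1.

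Whether the effects of both drugs added up on the log2 scale was tested as an interaction, the effect of erlotinib with YF454A minus its effect without. Replication genes had fallen with each drug. The fall with both was smaller than the sum. For MCM10, at 8.86 ± 0.059 in control, 8.14 ± 0.042 with erlotinib, 8.10 ± 0.028 with YF454A and 7.98 ± 0.083 with both (SD, n = 3 each), the interaction was 0.60 ± 0.074 (adjusted p = 0.00201), and for CDC45 it was 0.62 ± 0.074. The interaction was positive and past the threshold in 15 of 34 replication genes (32 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 5.49e-34; adjusted p = 0.0375 with an estimated correlation). It was also positive for RAD54L (0.96 ± 0.081, adjusted p = 0.000257) and BLM (0.66 ± 0.11) among 3 of 19 recombination genes (9 adjusted over the list alone). The same held for H2BC11 (0.85 ± 0.15) among 3 of 6 polyadenylated histones (3 adjusted over the list alone) and for HK2 (0.64 ± 0.10) among 2 of 21 glycolysis genes (4 adjusted over the list alone). Camera adjusted p-values for these 3 lists were 1.66e-10, 2.63e-05 and 3.66e-05 (adjusted p = 0.206, 0.16 and 0.356 with an estimated correlation).

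**Figure D3:**
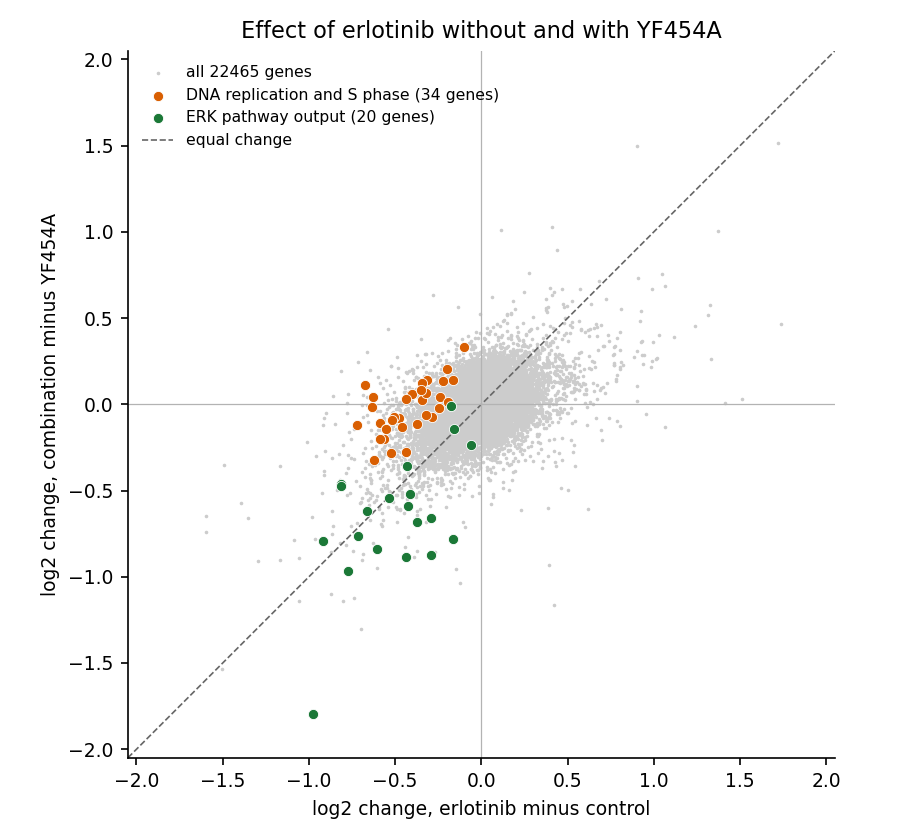
Log2 change with erlotinib minus control (horizontal axis) against combination minus YF454A (vertical axis) for all 22465 genes (grey), with 34 genes of DNA replication and S phase (orange), 20 of ERK pathway output (green) and the line of equal change (dashed). The replication genes have a median interaction of 0.40, the distance above the line, and DUSP6, which fell by 0.97 without and by 1.79 with YF454A, lies under it.

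Other genes had a negative interaction. CCND1 fell by 0.29 ± 0.049 with erlotinib, by 0.51 ± 0.049 with YF454A and by 1.38 ± 0.049 with both, an interaction of -0.58 ± 0.070 (adjusted p = 0.00178). The interaction was -0.82 ± 0.14 for DUSP6 (adjusted p = 0.0152) and -0.45 ± 0.089 for MYC (adjusted p = 0.0282), both of which YF454A alone had raised. It was -0.37 ± 0.063 for ERBB3 (adjusted p = 0.0142), which erlotinib alone had raised. In all, 5 of 20 ERK genes were negative (7 negative and 1 positive adjusted over the list alone). ASNS, PSAT1 and DDIT4, which rose with erlotinib, had interactions of -0.79 ± 0.076, -0.60 ± 0.075 and -0.61 ± 0.077 among 7 of 21 stress response genes (8 negative and 2 positive adjusted over the list alone). For AKR1B10 it was -0.64 ± 0.10 among 3 of 20 NRF2 targets (6 adjusted over the list alone), and AKR1B10 was also the 1 of 15 genes abundant in A549 cells (1 adjusted over the list alone). Camera adjusted p-values were 3.01e-05 for ERK output, 3.38e-07 for the stress response, 3.01e-05 for NRF2 targets and 0.028 for the A549 list. Of these the stress response alone passed with an estimated correlation (adjusted p = 0.356, 0.0375, 0.356 and 0.462 with an estimated correlation). With fry, ERK output (0.0971), NRF2 targets (0.0809) and the A549 list (0.233) did not pass. The settings followed for named genes leave out the 2-fold minimum and all transcript clusters. The largest negative interactions past the threshold in each of them were of SLC16A4 (-1.49 ± 0.12), KMO (-1.41 ± 0.15) and TFPI (-1.23 ± 0.14). The largest positive ones were of LINC00941 (1.14 ± 0.098) and the linker histone gene H1-4 (0.97 ± 0.11).

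For 3 more lists the camera calls were likewise lost with an estimated correlation and with fry. Mitosis genes were shifted upwards with a median interaction of 0.074 (camera adjusted p = 0.0273; adjusted p = 0.816 with an estimated correlation; fry 0.414), with AURKB at 0.46 ± 0.13 (adjusted p = 0.12, and 0.0114 with array weights). Of the 31 mitosis genes 0 had an interaction past the threshold (0 adjusted over the list alone). Without the same 4 arrays the direction of the mitosis list turned (camera adjusted p = 0.963). Inflammatory cytokines, with IL6 at 0.53 ± 0.094 and 2 of 21 positive (2 positive and 1 negative adjusted over the list alone), had camera adjusted p = 0.028 (adjusted p = 0.509 with an estimated correlation; fry 0.195; 0.0974 without the same 4 arrays). Epithelial genes were shifted downwards with a median of -0.063 although ELF3, the 1 of 22 past the threshold, was positive at 0.45 ± 0.085 (1 positive and 3 negative adjusted over the list alone; camera adjusted p = 0.0056; adjusted p = 0.462 with an estimated correlation; fry 0.162).

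In all, 369 genes had an interaction by limma, 186 positive and 183 negative, 10 of them of at least 2-fold. Camera called 11 lists, and 2 with an estimated correlation, and fry called 5. The count of genes was 229 without control 1, 208 without control 2, 245, 200 and 202 without erlotinib 1, 2 and 3, 167 without combination 2, 225 without combination 3 and 173 without YF454A 3. It moved less without control 3 (351), combination 1 (259), YF454A 1 (360) or YF454A 2 (279). The MYC interaction missed the threshold without control 1 (0.0522), control 2 (0.0683), control 3 (0.052), erlotinib 1 (0.0671), erlotinib 2 (0.0817), combination 1 (0.0675), combination 2 (0.0685), YF454A 1 (0.05) or YF454A 3 (0.0808). The ELF3 interaction (adjusted p = 0.0211) missed it without control 1 (0.0515), erlotinib 2 (0.0516), erlotinib 3 (0.0635), combination 1 (0.05), combination 2 (0.0639), combination 3 (0.0505) or YF454A 3 (0.0672). Without the same 4 arrays the calls of DUSP6 (0.0922), ERBB3 (0.114), HK2 (0.084) and ELF3 (0.0612) were lost.

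The effect of each drug was also set side by side without and with the other, in comparisons that share no array. For erlotinib, 194 genes were higher and 424 lower both without and with YF454A, where independent lists of the same sizes would share 16.6 and 49.9, and 16 genes moved in opposite directions. Across genes the correlation of the 2 sets of changes was 0.493. For YF454A, 2697 genes were higher and 2433 lower both without and with erlotinib, against 530 and 456 for independent lists, 28 moved in opposite directions and the correlation was 0.872. Genes are not independent replicates, and no p-value is attached to these correlations. DUSP6, HBEGF and NAV3 were among the genes that fell with erlotinib in both settings, and TYMS, CDCA7 and DOCK10 among those that fell with YF454A in both.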

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

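Chosen only after the results were seen were the tests of the array median and of the replicate number. The check of the cell line labels was fixed beforehand, but how to read its value was chosen after the results were seen. In the test of whether the effects of erlotinib and YF454A add up, 369 genes passed by limma and 11 lists by camera. With an estimated correlation 2 lists passed, DNA replication and the amino acid stress response (adjusted p = 0.0375 for each), and 5 passed by fry. The median interaction was -0.14 for ERK pathway output, 0.37 for polyadenylated histones, 0.40 for DNA replication, 0.074 for mitosis (a list whose direction turned without 4 arrays chosen after the data were seen), 0.27 for homologous recombination, -0.063 for epithelial genes, 0.11 for inflammatory cytokines, 0.11 for glycolysis, -0.12 for the amino acid stress response, -0.084 for NRF2 targets and -0.015 for genes abundant in A549 cells. Among the fixed genes the interaction passed for ERBB3 (-0.37), DUSP6 (-0.82), CCND1 (-0.58) and MYC (-0.45).

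Replication genes fell with each drug, and their fall with both was smaller than the sum. Compression near the floor of the array might produce this, but the 24 list members whose levels lay above the 75% quantile of all genes had a mean interaction of 0.390 (95% interval 0.275 to 0.505), and the whole list 0.396. A single array could also do so, but with each array left out in turn the lowest bound of the interval was 0.250. Both values argue against these explanations as the whole cause. That each drug alone already takes cells out of S phase remains open as a biological hypothesis, since cell cycle phase was not measured.

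Within groups the arrays deviated together along an axis that held 38.3% of the within-group variance, with control 3, erlotinib 3, YF454A 2 and combination 3 at one end. As a check on the replicate number, 11 of the 18 same-numbered pairs lay on the same side. A number that alone set the axis would put all of them there, but a partial effect need not. Control 1, erlotinib 1, YF454A 1 and combination 1 all lay on the other side (-7.57, -5.89, -11.4 and -5.27). Arrays numbered 2 fell on both sides, and so did those numbered 3, with YF454A 3 at -1.35. A partial effect of the replicate number therefore stays open. Over the 12 arrays the axis followed the array median, both as deviations from the group, with Pearson r = -0.837 and Spearman rho = -0.825 (exact within-group permutation p = 0.00694 for both, of 1296 permutations; r = -0.801 without control 3 and combination 3). The medians came from the same quantile normalized values as the axis, so they do not measure the raw brightness of an array. A shift shared by many genes enters both, so the link is partly built in and the permutation p does not compare independent measures. Whether RNA quality or hybridisation lay behind the axis therefore cannot be told from this link, and no biological explanation was tested.

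The descriptions of the control arrays name A549 cells. If the controls alone were A549, genes abundant in that line could be expected to be far higher there, but control minus treated was 0.054 (95% interval -0.179 to 0.286). This argues against a different line in the controls. Whether all 12 arrays might hold another line than the labels give stays open.

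With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2609 genes for erlotinib (highest of the other splits 1), 6609 for YF454A (1), 7427 for the combination (0), 6704 for the combination against erlotinib (0) and 1068 for the combination against YF454A (0), and 1 of 10 splits, the real one, reached each count. Each other split mixed arrays of both groups and so put the difference between them into the spread. Low counts there were to be foreseen, and they do not settle whether chance could give the real ones. For the interaction, 2 of 100 regroupings, the real one included, gave as many as 369 genes. Free regroupings put the effect of YF454A into the spread, and their median was 0 genes, so they do not settle whether chance could give the interaction. The other such regrouping gave 1889 genes, several times the real count, and points to a structure of the samples: it set 5 of the 6 arrays with YF454A on one side, so that it followed the effect of YF454A.

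Of 45063 transcript clusters not kept for the gene tests, 4584 changed in the combination against control by limma, 2386 of them higher. They include further clusters of genes that were tested, and their p-values were adjusted over all transcript clusters.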

How the results depend on the processing

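Leaving out 4 arrays (control 3, erlotinib 3, YF454A 2 and combination 3) and rescaling the arrays for the list tests were chosen only after the data were seen, as was the way array weights were estimated, since the default did not converge. Named genes were followed in every setting except the 2-fold minimum and all transcript clusters. Among 596 calls of named genes, 494 held in each of these settings and 102 were lost in some, 78 of them when 1 array was left out. Of the 644 pairs of gene and comparison, 0 turned direction while past the threshold in the main fit or in the other setting. Turns of pairs past it in neither were not counted. Without 1 array the counts ranged from 1821 to 2202 for erlotinib, 5816 to 6491 for YF454A, 6613 to 7020 for the combination, 5764 to 6139 for the combination against erlotinib, 566 to 1127 for the combination against YF454A and 167 to 360 for the interaction. The interaction count of 369 became 206 over all transcript clusters, 195 with median centring (191 shared), 1505 with array weights (366 shared) and 99 without the 4 arrays (86 shared). The count of 1068 for the combination against YF454A became 3167 with array weights, 659 with its 6 arrays alone and 666 without the 4 arrays, and the count of 2609 for erlotinib became 1712 without them. The causes were not tested, beyond the fewer arrays. A 2-fold minimum left 29, 329, 563, 365, 14 and 10 genes, in the order of the comparisons. With an estimated correlation camera called 4, 0, 0, 0, 3 and 2 lists (8, 3, 6, 3, 3 and 4 at an unadjusted p under 0.05), and fry called 19, 15, 17, 19, 11 and 5. The mitosis interaction turned direction without the 4 arrays (adjusted p = 0.963), and the cause was not tested. With the replicate number as a block (replicate block) the counts were 2667, 6692, 7462, 6772, 1131 and 345, and 8 calls of named genes were lost, among them EGFR with erlotinib (adjusted p = 0.0647), and 1 was gained. Between groups the labels link the samples by a number alone. Of 18 same-numbered pairs 9 had correlated deviations over 0.1, and 5 of 12 arrays matched their own number best. The median correlation was 0.082 for the same number and -0.030 for other numbers. Pairs numbered 1 were all positive (0.063 to 0.382), while those numbered 2 or 3 went both ways. With median centring or a further quantile normalization the median of all genes moved by under 0.1. With dim genes left out the counts were 2730, 6541, 7262, 6608, 1183 and 431.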

Other observations

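The further lists below were made after the largest changes on these same arrays had been seen, and their camera p-values are not adjusted. The test of other histone genes was itself chosen only after the result was seen. WIPI1 and CALCOCO1 led the rises with YF454A, and a further list of 37 autophagy and lysosome genes, made without the genes already seen, was tested. Of these, 25 rose and 2 fell with YF454A, with a median of 0.29. GABARAPL1 rose by 1.21 ± 0.093, GABARAPL2 by 0.93, RB1CC1 by 0.82, GABARAP by 0.78, OPTN by 0.78, MAP1LC3B by 0.72 and ULK1 by 0.55, while ULK2 fell by 0.86 and SQSTM1, an autophagy receptor, by 0.20. The list was higher (camera p = 1.27e-08; p = 0.0136 with an estimated correlation). It was also higher with erlotinib alone, where 9 rose and 2 fell, with a median of 0.11 (camera p = 1.53e-05; p = 0.0436 with an estimated correlation). When erlotinib was added to YF454A 2 of 37 rose, with a median of 0.025 (camera p = 0.334; p = 0.607 with an estimated correlation). The interaction of the list was negative (camera p = 0.00017), a call lost with an estimated correlation (p = 0.0711). YF454A may raise autophagy genes as a group, and erlotinib without YF454A to a smaller median, a hypothesis for these cells and this time, and autophagy itself was not measured.

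CFB and IFI6 rose when erlotinib was added to YF454A, and 24 interferon gamma response genes, made without genes already seen, were tested. PARP9 rose by 0.56, APOL6 by 0.47, C1S by 0.46, IRF1 by 0.46, C1R by 0.41 and GBP1 by 0.39, and 7 of 24 rose (camera p = 1.55e-07; p = 0.000822 with an estimated correlation). With erlotinib alone 9 of 24 rose, with C1S at 0.70 and GBP1 at 0.62. In that comparison the camera p of the list was 8.23e-09. Erlotinib may raise part of this response both without and with YF454A.

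Histone genes were among the largest positive interactions. Of 24 other H1 and core histone genes, 5 had a positive interaction past the threshold: H2BC15 (0.59), H1-5 (0.58), H2AC14 (0.46), H2AC16 (0.45) and H2AC20 (0.40). The median was 0.42 (camera p = 5.76e-13; p = 0.00936 with an estimated correlation). The list was lower with erlotinib alone (camera p = 2.61e-07; p = 0.0413 with an estimated correlation) and with YF454A alone (camera p = 3.8e-07; p = 0.0435 with an estimated correlation). Histone transcripts could follow the replication genes, whose median interaction was 0.40, but they are closely similar in sequence and are not separate measurements.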
